A study of Dugesia japonica with 157 samples.

How the data were processed

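The series holds 157 libraries from the planarian flatworm Dugesia japonica, strain AF, each made from 1 tissue section of a whole animal. Per the labels' protocols, RNA was taken up with the Direct-TRI procedure and turned into libraries with Lasy-Seq version 1.1, a multiplexed RNA-seq method for many small samples, from polyadenylated RNA. The labels give 78 sections in order from anterior to posterior, 28 from dorsal to ventral and 51 from right to left, and name no replicate animals for any of the 3 directions.

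The authors deposited 1 table of estimated counts per direction, with 25566 rows that carry the same identifiers in each table. Per the submitters' processing notes, bcl2fastq 2.20.0, fastp 0.21.0, BWA 0.7.17-r1188 and Salmon were used, and the Salmon version, the role of each tool and the reference transcript set are not given in the sources used here. In the deposited estimated counts, 1028 of 4013862 values (0.0256%) were not whole, and they were rounded before any test. Column totals differed widely, as in tables not scaled to depth. Of the 157 columns, 150 were matched to 1 section each. The names of the other 7, all in the anterior-posterior table, are a section's description with a suffix, and when punctuation is ignored they equal the description of another section. They were counted as belonging to the anterior-posterior axis with no position and entered no test, which leaves sections 1 to 7 without data. Read by the suffix, which all 157 columns carry, they would be sections 1 to 7. The other sections that they match have columns of their own. These 7 columns were left out to keep to the name rule, after results with all 78 sections had been seen. Identifiers have a first part and a suffix, with 19543 distinct first parts. The tables do not pair identifiers with gene names, so the marker lists fixed beforehand could not be matched, their list counts and set tests were not run, and identifiers are printed as deposited. Where rows are near-identical copies of 1 gene, reads could have been split between them, and such rows are uncertain.

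Sections whose total was under 20% of the median total of their series were left out of the tests. Each series was divided by section number into 3 equal parts of all labelled sections, the anterior part thus losing sections 1 to 7, called the first, middle and last part and named by their place (anterior, middle and posterior part, for example). A gene, meaning a row of the table, was tested when it had 5 or more counts in at least 10% of the kept sections. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (R 4.3.3), using its quasi-likelihood F-test and Benjamini-Hochberg adjustment within each test, and a gene was called at an adjusted p under 0.05. For each series there were 3 tests, of a natural spline in section number with 4 degrees of freedom (position-dependent genes), of the first part against the last, and of the middle part against the mean of the end parts. The standard error of a log2 fold change was read from its F statistic. CPM values are counts scaled to depth by edgeR with the TMM factors. The series were never compared with each other in level.

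Sections stand in for replicates. The p-values therefore measure the spread between sections of a series and say nothing of the spread between animals. Library numbers in the labels follow section order, so a drift with library order would follow position as well. Limits and floors cover counting error only. For a gene with 0 counts in the lower region, a bound on the fold was computed against a floor of 3 counts over all sections of that region. For 1 to 3 counts in the lower region, the ratio of pooled CPM is given with an exact Poisson interval (95%) of the lower count.

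Identifiers named in the text are, per test and direction, the 2 with the largest absolute log2 fold change among called genes with a mean of at least 10 CPM in the higher region and the same sign in odd-numbered and even-numbered sections fitted apart. The peak of a named gene is the section with the highest 5-section running mean of log2(CPM + 1).

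Similarity of sections was the Pearson correlation of log2(CPM + 1) across genes, centred per gene. The mean over adjacent sections was tested by permuting the section order, one-sided, with 100000 resamples. Sections mirrored about section 26 were tested in the same way by permuting the left sections, with the 7 central sections left out. Calls were compared between series with Fisher's exact test, two-sided, in 40 tests adjusted together. Differences between the ventral and dorsal shares of a list were tested apart from these with the same test. They were not fixed beforehand and were adjusted only among themselves. Genes called on 1 series were also placed on the others by their median log2 fold change, set against 2000 random lists matched on mean expression.

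The fit was tested on simulated counts with 200 changed genes. For the comparison of the anterior and posterior parts (13781 genes), with dispersions from the trend, 92% of genes changed 16-fold and 33% of genes changed 4-fold were recovered, and 32 unchanged genes were called. With gene-wise dispersions, 92% and 38% were recovered and 118 unchanged genes were called, and the middle against the ends and the spline called 189 and 540 unchanged genes. For the dorsal and ventral parts with dispersions from the trend (18291 genes), 84% of genes changed 16-fold and 30% of genes changed 4-fold were recovered, with 8 unchanged genes called, and gene-wise dispersions gave 76% and 22%, with 1 unchanged gene. For the right and left parts with dispersions from the trend (16463 genes), the shares were 91% and 45%, with 16 unchanged genes called, and gene-wise dispersions gave 83% and 33%, with 12 unchanged genes. Each fit was also repeated on 99 shuffled orders of the same sections.

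Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, the DESeq2 test, no filter on low genes, all sections, a minimum of 50% of the median total, the section total as a covariate, odd-numbered or even-numbered sections alone, a spline with 6 degrees of freedom, a linear trend, 5 parts in place of 3, Spearman correlation, thinned counts for the similarities, other midlines and calls at an adjusted p under 0.001. Added after the data were seen were a stricter gene filter, in which 5 or more counts were needed in at least 1 of every 3 kept sections, limma-trend (limma 3.58.1, prior count 2), rows summed by the first part of the identifier, the outermost 3 kept sections at each end left out, TMMwsp scaling, thinned counts for the tests, sections 55 to 59 of the anterior-posterior series left out, right sections against mirrored left sections, re-centred parts and, in the dorsal-ventral and right-left series only, each kept section left out in turn. Permutations, overlaps and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.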

Results

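Dugesia japonica is a freshwater planarian, a flatworm with a head at the anterior end and, in the trunk, a pharynx through which it feeds. Whole animals were cut into serial sections along the 3 body axes, and polyadenylated RNA of each section was sequenced, so that a transcript's place along an axis could be read from the section numbers. The anterior-posterior series held 78 sections, the dorsal-ventral series 28 and the right-left series 51. No replicate animals were labelled. With punctuation ignored, the names of 7 columns of the anterior-posterior series matched more than 1 section, and these columns were left out. The other sections matched in this way have columns of their own. The loss thus comes from the name rule and is not a gap in the deposited tables. Only sections 8 to 78 are covered, and the foremost 7 sections of the head, where the suffix of the names would place these columns, are missing from every result. They were left out after results with all 78 sections had been seen, in which more genes were called between the ends and some of the named identifiers were others.

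Depth varied strongly between sections. Totals ran from 79382 to 12945391 estimated counts along the anterior-posterior axis (71 sections, median 787073), from 275287 to 26807303 along the dorsal-ventral axis (median 2325710) and from 19222 to 13052596 along the right-left axis (median 1102511). Left out for a low total were 2, 7 and 14 sections, in that order of the axes, so that 69, 21 and 37 sections were tested. Among them were the outermost sections, 1 to 3, 27 and 28 of the dorsal-ventral series. In the right-left series they included sections 1 to 5 and 49 to 51. The kept sections had a median of 7628 detected genes in the anterior-posterior series, 15279 in the dorsal-ventral series and 12727 in the right-left series. Middle sections were deeper than end sections in each series. In the dorsal-ventral series the median total was 4323922 in the kept dorsal sections, 14600693 in the middle and 1874284 in the ventral sections.

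**Figure D1:**
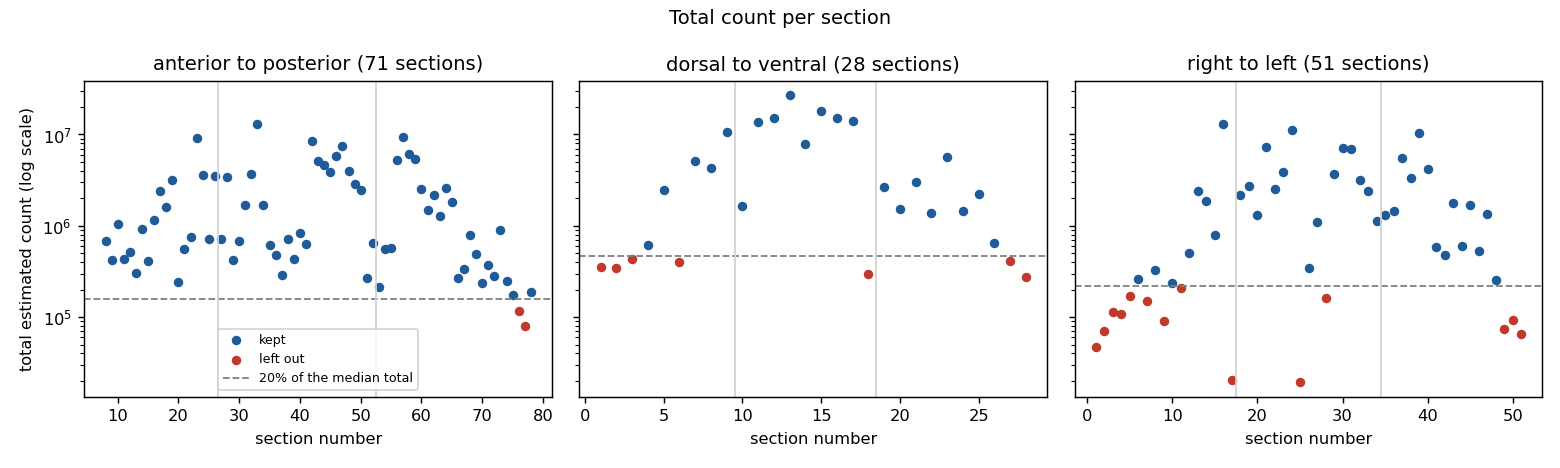
Total estimated count of each section (log scale) against section number in the 3 series. Blue points are the 69, 21 and 37 kept sections, red points those left out, the dashed line is 20% of the median total, and grey lines part the parts.

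Neighbouring sections resembled each other more than sections in shuffled order in all 3 series. The mean correlation of adjacent sections was 0.103 along the anterior-posterior axis (67 pairs), 0.247 along the dorsal-ventral axis (18 pairs) and 0.135 along the right-left axis (30 pairs). Permutation of the order gave a one-sided p of 1e-05 in each series, the smallest that 100000 resamples can give, and shuffled means of -0.0103, -0.0317 and -0.0185. With counts thinned to 1 total per series, the mean correlations were lower, at 0.0633, 0.155 and 0.061, with the same permutation p. These are correlations across genes, which are not independent replicates. Over short distances similarity fell: in the dorsal-ventral series it was 0.150 (SD 0.259, 34 pairs) at a distance of 2 to 3 sections and -0.205 (SD 0.151, 70 pairs) at 8 to 14 sections, and it rose again to -0.0617 (SD 0.129, 30 pairs) at 15 to 28 sections.

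The anterior-posterior series asked which transcripts belong to the head side, trunk or tail end, without the foremost sections. Between the anterior part (19 sections, from section 8 on) and the posterior part (24 sections), 238 genes were higher anteriorly and 98 posteriorly, of 13781 tested. DjGI014810_001 was a mainly anterior transcript, at 77.8 ± 117 CPM (SD, n = 19) in the anterior part, 3.93 ± 10.3 CPM (SD, n = 26) in the middle and 0.444 ± 1.68 CPM (SD, n = 24) posteriorly, with its peak at section 11 (log2 fold change 7.65 ± 1.10 SE, adjusted p = 2.27e-06). DjGI017679_001 was found in 10 of 19 anterior and 22 of 26 middle sections, with means of 26.4 ± 49.5 CPM and 42.6 ± 40.7 CPM and its peak at section 25, and had 1 count in the posterior part (counting interval of the ratio 569 to 125220, adjusted p = 5.68e-09). With 5 parts in place of 3 its log2 fold change was 1.58 and the call was lost (adjusted p = 0.677). The direction was opposite for DjGI003571_001, whose mean was 22.8 ± 64.6 CPM in the posterior part against 0.137 ± 0.525 CPM in the anterior part (log2 fold change -6.34 ± 1.21 SE, adjusted p = 0.000568), although section 69 alone held 54.0% of its summed CPM. DjGI015191_001 reached 26.2 ± 94.8 CPM posteriorly and 0.935 ± 3.36 CPM anteriorly (log2 fold change -4.80 ± 1.29 SE, adjusted p = 0.0242), with 54.5% of its summed CPM in section 78, and it lost its call under 7 of 12 alternatives. The count and its direction depended on the method: DESeq2 called 81 anterior and 93 posterior genes, and the odd-numbered sections alone gave 9 genes and the even-numbered sections 43. However, DESeq2 gave no adjusted p for 7748 of the 13781 genes, so its count covers fewer genes. A minimum of 50% of the median total gave 125 anterior and 128 posterior genes. Larger counts came from the section total in the model (714 anterior and 177 posterior), from leaving out sections 55 to 59 (822 and 139) and from 5 parts in place of 3 (1086 and 522).

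The middle part held 183 genes above the mean of the ends, and 36 genes were higher at the ends. With the section total in the model these were 242 and 296. DjGI016985_001 averaged 126 ± 252 CPM (SD, n = 26) in the middle part, 0.0172 ± 0.0748 CPM anteriorly and 2.27 ± 10.9 CPM posteriorly, and peaked at section 37 (log2 fold change 8.35 ± 0.91 SE, adjusted p = 1.75e-10). DjGI011378_001 was counted only in the middle part, with 968 counts in 11 of 26 sections and 0 counts in the end sections, so it was at least 348-fold higher there (adjusted p = 1.9e-06). Of the transcripts higher at the ends, DjGI004643_001 was mainly anterior, at 34.6 ± 53.9 CPM against 1.01 ± 2.27 CPM in the middle and 4.75 ± 8.24 CPM posteriorly (log2 fold change of the middle against the ends -3.35 ± 0.70 SE, adjusted p = 0.00109). DjGI014573_001 had the same order, 115 ± 138, 13.8 ± 13.9 and 23.2 ± 37.8 CPM from anterior to posterior (log2 fold change -1.86 ± 0.49 SE, adjusted p = 0.0239), and lost its call under 6 of 15 alternatives. A spline in section number called 3114 genes in all. In simulated counts with dispersions from the trend, 43 unchanged genes were called between the middle and the ends and 130 by the spline. With gene-wise dispersions these were 189 and 540, so many of the 219 middle calls are uncertain.

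Shuffled orders of the same sections called a median of 88 genes between the end parts, 97 between the middle and the ends and 511 by the spline, and at most 813, 279 and 998. With the stricter gene filter, added after the data were seen, 94 genes differed between the ends (62 anterior and 32 posterior), 95 between the middle and the ends and 953 by the spline, against at most 2, 14 and 19 in 9 shuffled orders.

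The dorsal-ventral series set the upper side of the animal against the lower side, without the outermost sections. The dorsal part (5 sections) and the ventral part (8 sections) differed in 146 of 18291 genes, 90 of them higher dorsally and 56 ventrally. DjGI000828_002 fell from 13.3 ± 9.38 CPM (SD, n = 5) dorsally through 5.33 ± 3.89 CPM (SD, n = 8) in the middle to 0.279 ± 0.788 CPM (SD, n = 8) ventrally (log2 fold change 4.89 ± 1.01 SE, adjusted p = 0.0145). DjGI010983_001 showed the same order, 13.2 ± 7.92, 2.71 ± 1.69 and 0.545 ± 1.54 CPM (log2 fold change 4.45 ± 1.03 SE, adjusted p = 0.033). Both ventral transcripts had 0 counts in the dorsal sections. DjGI011591_001 reached 25.8 ± 20.5 CPM ventrally and was at least 215-fold higher there (adjusted p = 0.0018), and DjGI006405_001 reached 14.3 ± 20.3 CPM and was at least 143-fold higher (adjusted p = 0.047), but lost its call under 6 of 14 alternatives. The direction was not stable, with 57 dorsal and 72 ventral genes when the section total was in the model. With 5 parts there were 9 and 14, but the outermost dorsal part then held only 2 kept sections. The count changed when single sections were left out: it was 66, 63 and 52 without section 7, 8 or 9, and 233 and 286 without section 23 or 26. Without section 22 or 24 it was 95 and 96. These 2 values are close to the 103 and 99 without section 13 or 16, middle sections outside this comparison. With all 28 sections, including those with low totals, 37 genes were called (14 dorsal and 23 ventral), and neither dorsal transcript was among them (adjusted p = 0.0969 and 0.105).

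More genes separated the middle from the ends of the dorsal-ventral series, 857 higher in the middle and 807 higher at the ends. This even split depended on the settings: it was 638 and 129 with all sections, 1052 and 414 with limma-trend and 670 and 883 with thinned counts. DjGI007068_001 averaged 18.7 ± 15.7 CPM (SD, n = 8) in the middle and 7.09 ± 6.04 CPM ventrally, and had 0 counts dorsally, so the middle was at least 152-fold above the dorsal part (adjusted p of the middle against the ends 0.000238). DjGI019005_001 had 11.5 ± 4.58 CPM in the middle, 2.57 ± 3.91 CPM dorsally and 0 counts ventrally, at least 81.2-fold below the middle (adjusted p = 0.00087). DjGI016745_001 was lower in the middle, at 2.09 ± 1.69 CPM against 14.8 ± 13.0 CPM dorsally and 30.1 ± 63.5 CPM ventrally (log2 fold change -3.28 ± 0.80 SE, adjusted p = 0.00938), and section 26 held 56.3% of its summed CPM. DjGI015500_001 had 1.24 ± 1.09 CPM in the middle, 11.3 ± 11.1 CPM dorsally and 11.9 ± 7.45 CPM ventrally (log2 fold change -3.26 ± 0.84 SE, adjusted p = 0.0137). With the section total in the model, 192 genes (153 higher in the middle and 39 at the ends) were called in place of 1664, 179 of them among the 1664, and DjGI016745_001 and DjGI015500_001 lost their calls (adjusted p = 1 and 0.712). With all sections DjGI007068_001 and DjGI019005_001 lost theirs (log2 fold change 2.46 and 2.79, adjusted p = 0.0794 and 0.0722). The spline called 2996 genes. Shuffled orders called at most 1 gene between the ends, 2 between the middle and the ends and 64 by the spline.

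**Figure D2:**
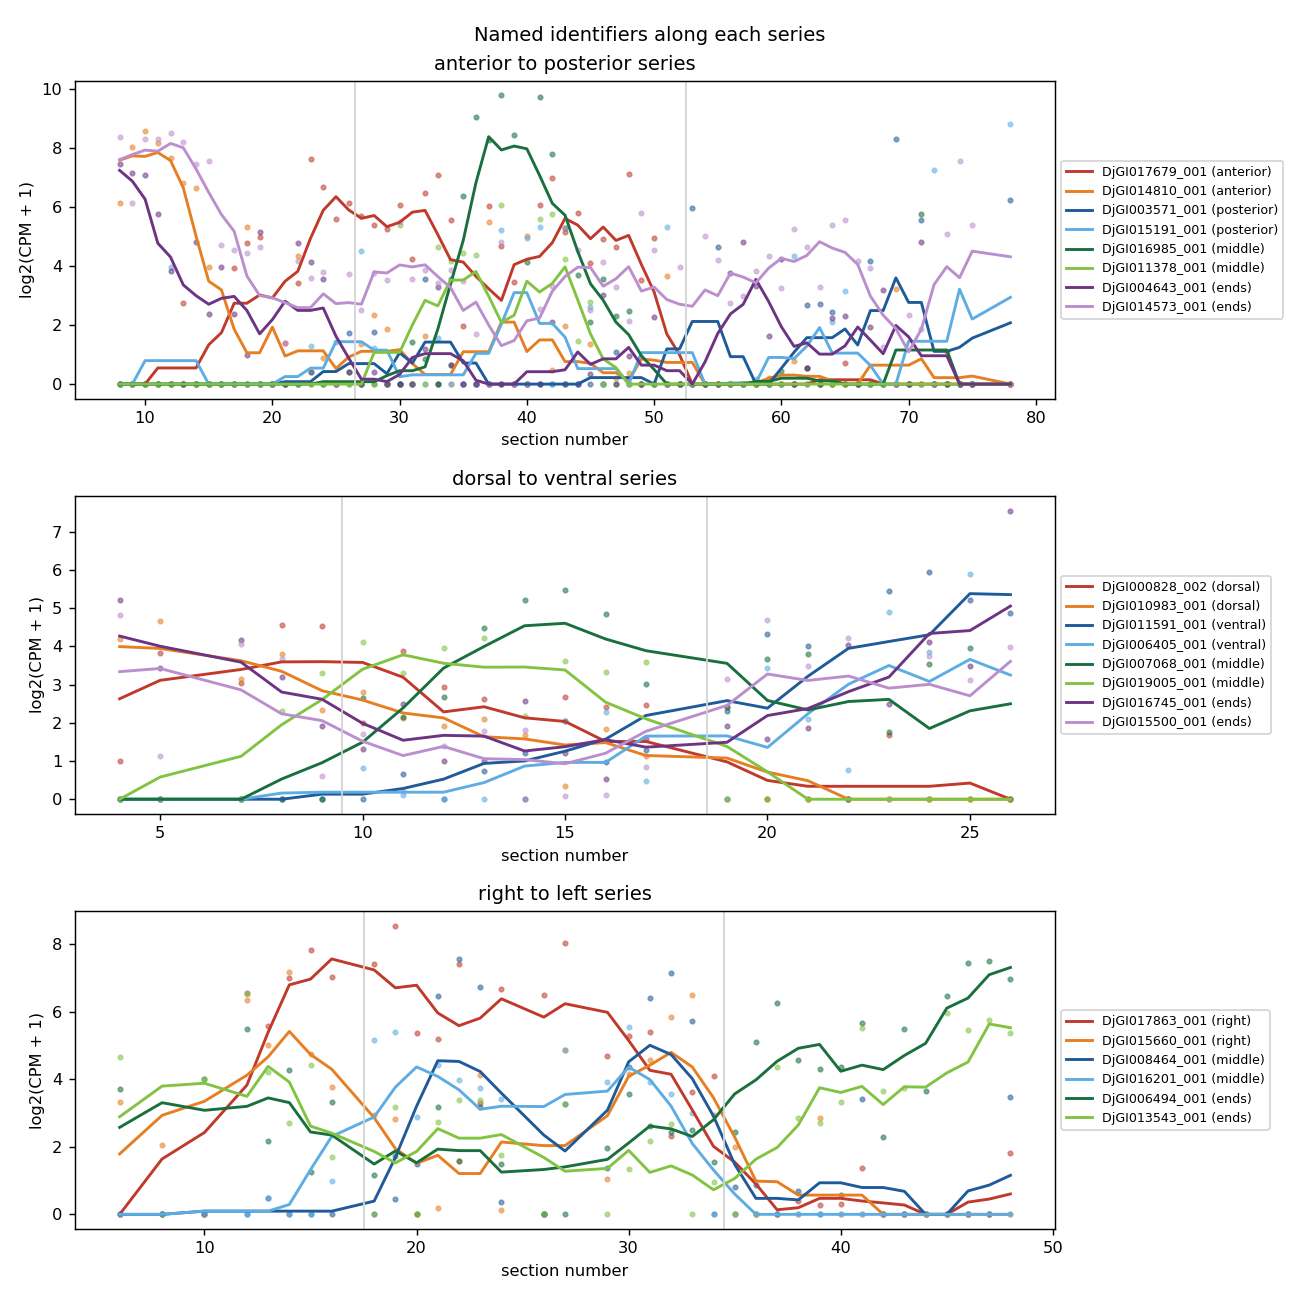
log2(CPM + 1) of the named identifiers against section number in the 3 series, with points for the kept sections, lines for 5-section running means and grey lines between the parts. DjGI014810_001 peaks at section 11 and DjGI016985_001 at section 37 of the anterior-posterior series.

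The right-left series showed few differences between its right and left parts, but the count depended on the settings. Of 16463 genes, 7 were higher in the right part (8 sections) than in the left part (14 sections) and 0 were higher on the left. At an unadjusted p under 0.05 the test gave 1325 genes, DESeq2 called 39 genes (10 right and 29 left) and limma-trend called 0. However, DESeq2 gave no adjusted p for 11809 of the 16463 genes, so its count covers fewer genes. All 51 sections gave 38 right and 9 left genes. With 5 parts in place of 3, which compare only the outermost kept sections, there were 220 right and 533 left genes. The outermost right part then held only 3 kept sections, and the median log2 fold change over all genes was -1.36. This larger count therefore cannot be laid to the place of the sides alone. DjGI017863_001 averaged 78.2 ± 82 CPM (SD, n = 8) on the right, 92.7 ± 108 CPM (SD, n = 15) in the middle and 0.350 ± 0.755 CPM (SD, n = 14) on the left (log2 fold change 8.48 ± 0.92 SE, adjusted p = 1.02e-07). With 5 parts in place of 3 the call was lost, and the log2 fold change had no determined sign (-2.66 ± 8.30 SE, adjusted p = 0.872). DjGI017863_001 had 0 CPM in the outermost kept right sections (6, 8 and 10). It was also called higher in the middle than at the sides (log2 fold change 4.4, adjusted p = 9.68e-06). So was DjGI016985_001, another of the 7 genes (log2 fold change 5.5, adjusted p = 2.9e-06). DjGI015660_001 averaged 38.7 ± 50.3, 16.9 ± 25.4 and 0.657 ± 1.79 CPM from right to left (log2 fold change 5.29 ± 0.96 SE, adjusted p = 0.00816). Without section 39 the count was 4, and 1 of 99 shuffled orders gave more, with 32 genes.

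The middle of the right-left series stood apart from the sides in 163 genes, 128 higher in the middle and 35 higher at the sides. DjGI008464_001 averaged 46.4 ± 61.9 CPM (SD, n = 15) in the middle, 0.0492 ± 0.139 CPM on the right and 1.6 ± 3.52 CPM on the left (log2 fold change 7.24 ± 1.03 SE, adjusted p = 1.31e-05). DjGI016201_001 had 17.4 ± 14.1 CPM in the middle, 0.170 ± 0.351 CPM on the right and 0 counts on the left, at least 219-fold below the middle (adjusted p = 1.51e-07). Toward the sides, DjGI006494_001 averaged 13.1 ± 14.3 CPM on the right and 60.9 ± 60.5 CPM on the left against 3.56 ± 3.30 CPM in the middle (log2 fold change -2.77 ± 0.51 SE, adjusted p = 0.00092). DjGI013543_001 had 22.1 ± 29.3, 3.69 ± 3.78 and 22.0 ± 21.9 CPM from right to left (log2 fold change -2.48 ± 0.65 SE, adjusted p = 0.0468) and lost its call under 9 of 14 alternatives. The spline called 1510 genes. The odd-numbered sections alone gave 1 gene and the even-numbered sections 23 for the middle against the sides. Shuffled orders called at most 33 genes between the middle and the sides and 470 by the spline.

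**Figure D3:**
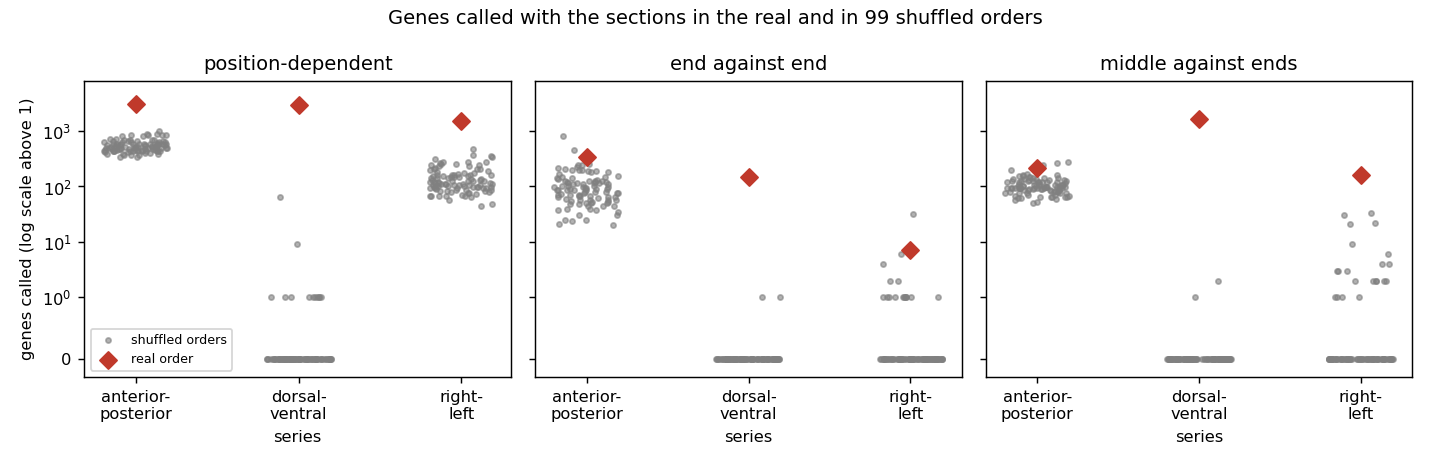
Genes called by each of the 3 tests (log scale above 1) with the sections of each series in the real order (red diamonds) and in 99 shuffled orders (grey points). The real counts of 2996, 146 and 1664 genes in the dorsal-ventral series lie above all shuffled counts, and in the anterior-posterior series shuffled orders reach 813 genes between the ends, above the real 336, and 279 between the middle and the ends, above the real 219.

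Planarians are bilaterally symmetric, and sections at equal distance from the centre of the right-left series were compared. The mean correlation of 13 mirrored pairs about section 26 was 0.0587, against -0.0236 when the left sections were shuffled (permutation test, one-sided p = 0.0189). The value depended on the assumed midline: it was 0.0487 at section 27 (p = 0.0131, permutation test), 0.0371 at section 25 (p = 0.0949, permutation test), 0.00229 at section 28 (p = 0.130, permutation test) and -0.0688 at section 24 (p = 0.858, permutation test).

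Genes called on 1 axis were often called on another. Genes are not independent replicates, so the p-values and random ranges given here may overstate the certainty. Anterior genes shared 11 of the 55 ventral genes tested on both axes, where 0.951 were expected (Fisher's exact test, adjusted p = 2e-08), and 10 of the 78 dorsal genes, where 1.35 were expected (adjusted p = 3.93e-06). The ventral and dorsal shares were 20.0% and 12.8%, with no difference detected (Fisher's exact test, adjusted p = 0.335), although the ventral share had been larger, with an adjusted p under 0.05, before the 7 columns were left out. Genes of the anterior-posterior middle included 11 of 78 dorsal genes and 1 of 55 ventral genes (Fisher's exact test, adjusted p of the difference 0.0198). The differences between ventral and dorsal shares given here were not among the tests fixed beforehand, and were adjusted only among themselves. Of the 93 genes higher in the right-left middle and tested on both axes, 24 were anterior (1.58 expected, adjusted p = 1.64e-20) and 20 belonged to the anterior-posterior middle (1.23 expected, adjusted p = 8.26e-18). Genes of the lateral sides shared 7 of 56 ventral genes and 0 of 90 dorsal genes (adjusted p of the difference 0.00383), and genes of the right-left middle likewise shared more ventral than dorsal genes, 8 of 56 and 2 of 90 (adjusted p = 0.0145). For the right-left middle, whole lists went the other way. Its 126 genes tested on both axes leaned dorsally (median log2 fold change 0.28, random lists -0.12 to 0.22). In the right-left series the 90 dorsal genes leaned to the middle (0.61, random lists 0.04 to 0.24). For the sides, whole lists went the same way as the shared genes. The 32 genes of the sides leaned ventrally (-1.06, random lists -0.28 to 0.39), and the 56 ventral genes leaned to the sides (-0.14, random lists 0.03 to 0.27). DjGI017863_001, called on the right and in the right-left middle, was also higher ventrally (log2 fold change of dorsal against ventral -7.14, adjusted p = 0.0428) and in the anterior-posterior middle (log2 fold change 2.88, adjusted p = 0.00542), and on that axis it was higher anteriorly than posteriorly (log2 fold change 3.63, adjusted p = 0.0126). DjGI006494_001 and DjGI013543_001, both lateral, were ventral as well, with log2 fold changes of -4.83 (adjusted p = 0.0113) and -6.17 (adjusted p = 0.0117). Of the 40 tests between axes, 17 passed an adjusted p of 0.05, and 14 of them shared more genes than expected. Fewer than expected were shared by genes of the anterior-posterior middle with those of the dorsal-ventral middle (3 against 10.2, adjusted p = 0.0350) and with those of the dorsal-ventral ends (2 against 9.73, adjusted p = 0.0204). Genes of the right-left middle and of the dorsal-ventral ends shared 0 genes, where 5.59 were expected (adjusted p = 0.0204). With the stricter gene filter the first and the last of these lost their calls (adjusted p = 0.111 and 0.272).

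**Figure D4:**
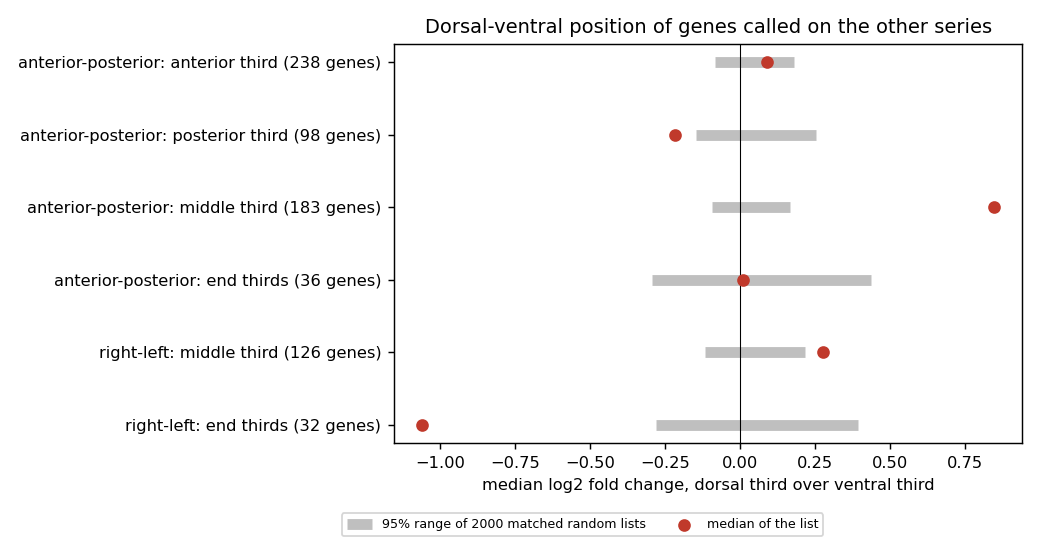
Median log2 fold change of the dorsal over the ventral part (red points) for lists of genes called on the other 2 series, with the 95% range of 2000 random lists matched on mean expression (grey bars). The 238 anterior genes lie at 0.09, the 183 genes of the anterior-posterior middle at 0.85 and the 32 genes of the right-left sides at -1.06.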

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

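Of the results given here, those from the stricter gene filter, limma-trend, trimmed ends, thinned counts for the tests, sections 55 to 59 left out, mirrored left sections and single sections left out (not run for the anterior-posterior series) come from tests chosen only after the data were seen. No paired analysis was possible because section numbers are positions on 3 separate axes and pair no libraries. Counts are given in the order position-dependent, end against end and middle against ends, and where a count is not given it was not run or stayed within 1.5 times the reported count. A count within this range can still be divided differently between the 2 directions. The cause was not tested except where fewer sections or another number of genes entered the fit by construction. DESeq2 size factors, TMMwsp scaling, summed identifiers and a spline with 6 degrees of freedom, where run, left all 9 counts within that range, and the adjacent-section similarities kept their side of the threshold under Spearman correlation and thinned counts. Thinned counts nevertheless lowered these similarities in each series.

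In the anterior-posterior series, no filter on low genes gave 8237, 2384 and 1824 genes, the stricter filter 953, 94 and 95, the DESeq2 test 1239, 174 and 126, limma-trend 1811, 50 and 120, and thinned counts 950, 159 and 103. The DESeq2 test gave no adjusted p for 3741, 7748 and 1603 genes. Odd-numbered sections gave 1026 and 9 and even-numbered sections 1633 and 43 position-dependent and end genes. A minimum of 50% of the median total gave 1552 position-dependent genes, a linear trend 507, and trimmed ends 1445 with 202 end genes. With that minimum there were 253 end genes, 125 anterior and 128 posterior in place of 238 and 98. Of these, 147 were among the reported calls. For the end and middle tests the section total as covariate gave 891 and 538, the latter with 242 genes higher in the middle and 296 at the ends in place of 183 and 36, and a division into 5 parts 1608 and 961. Without sections 55 to 59 there were 961 end genes.

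In the dorsal-ventral series, all sections gave 4895, 37 and 767 genes, odd-numbered sections 1024, 20 and 353, even-numbered sections 284, 18 and 190, and trimmed ends 1258, 246 and 678. The section total as covariate gave 1657 position-dependent and 192 middle genes, DESeq2 465 end and 2512 middle genes, and a linear trend 148 genes. DESeq2 gave no adjusted p for 2175 genes in the end test and 2874 in the middle test. For end genes, a minimum of 50% of the median total gave 347 and a division into 5 parts 23, with only 2 kept sections in the outermost dorsal part. With each section left out in turn, end genes ran from 52 to 286 and middle genes from 1111 to 2108.

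In the right-left series, no filter gave 3649, 17 and 363 genes, all sections 5530, 47 and 249, odd-numbered sections 369, 1 and 1, even-numbered sections 579, 1 and 23, limma-trend 2574, 0 and 251, and thinned counts 882, 3 and 107. DESeq2 gave 39 end and 250 middle genes, with no adjusted p for 11809 and 10533 genes, and the stricter filter gave 4 and 79. A division into 5 parts gave 753 and 1513, with only 3 kept sections in the outermost right part. A minimum of 50% of the median total gave 884 position-dependent and 63 middle genes, trimmed ends 620 and 62, a linear trend 100, the section total as covariate 21 end genes, and mirrored left sections 2. With each section left out in turn, end genes ran from 4 to 10 and middle genes from 118 to 194. The mirrored similarity was -0.0688 with the midline at section 24, 0.0371 at section 25 and 0.00229 at section 28, and with thinned counts about section 26 it was 0.0118 (permutation test, p = 0.00945) in place of 0.0587.

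With calls at an adjusted p under 0.001, 3 tests between axes passed in place of 17. Of 304 values of the named identifiers under alternatives, 236 kept their call, 67 lost it with the same sign and 1 changed sign: DjGI017863_001 (-2.66 with an SE of 8.30, division into 5 parts, so its sign is not determined). Alternatives under which an identifier was not tested or had no adjusted p are not among these values. With the stricter gene filter, DjGI014810_001, DjGI003571_001, DjGI015191_001, DjGI016985_001, DjGI011378_001 and DjGI008464_001 were not tested. With thinned counts, DjGI003571_001, DjGI015191_001, DjGI011378_001 and DjGI004643_001 were not tested. Smaller changes were often missed, and with dispersions from the trend 4-fold changes were recovered for 33%, 30% and 45% of simulated genes in the 3 series, in the order above. The 7 anterior-posterior columns left out for their names, which the suffix would place at sections 1 to 7, are in none of these alternatives. The alternative pseudocount did not apply, because the tables hold counts.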

Other observations

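Tests chosen only after the result was seen were the oblique body axis, the thinned counts and the shuffled orders. The section total in the model was fixed before the data were examined, but was taken up as an explanation of the dorsal-ventral middle after its result was seen. Position on 1 axis went with position on another for some lists of genes. The 824 genes of the dorsal-ventral middle tested in the right-left series had a median log2 fold change of 0.66 between its middle and its sides, with 757 above 0, against 0.11 to 0.18 for matched random lists. In reverse, the 126 genes of the right-left middle had a median of 0.32 between the dorsal-ventral middle and ends, inside the range of random lists (0.11 to 0.45). Middle sections were deeper than end sections in each series. The section total was not in the model for these list comparisons, so a shared dependence on it stays open. The 55 ventral genes tested in the anterior-posterior series had a median of -0.45 between its middle and its ends, with 7 above 0 (random lists -0.06 to 0.15). The 78 dorsal genes went the other way, at 0.23 with 55 above 0 (random lists -0.04 to 0.13).

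The right part held 7 called genes and the left part 0. With the left sections limited to mirrors of kept right sections about section 26, the median log2 fold change of the 7 genes was 5.95 (5.83 with all left sections). Only 2 of them kept their calls with fewer left sections (8 in place of 14). The 7 genes were called from the same right sections and from left sections that include the mirrored ones, so this median could hardly fall. Unequal distance of the kept sections from section 26 therefore stays open as a cause. A shifted midline stays open: about section 25.5 the median was 5.96, but this centre came from genes called in the middle part, which holds it near section 26, and larger shifts were not tested. A body axis oblique to the sections remains a candidate explanation: among genes of the right-left middle, 23 anterior genes were centred at section 26.0 and 19 genes of the anterior-posterior middle at section 22.7 (permutation test, 100000 resamples, two-sided p = 2e-05). The latter list held 2 of the 7 genes, and without them the centres were 26.0 and 23.0 (p = 6e-05), but genes are not independent replicates, and a bent body or an organ off the midline stays open, as does any biological explanation, which was not tested.

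More genes separated the middle of the dorsal-ventral series from its ends (1664) than separated the ends (146). After thinning to equal totals, 86.3% of the 1488 calls still tested were kept, which argues against unequal numbers of counts as the whole cause for those genes. Without the 10 most abundant genes 99.94% of all calls were kept. TMM scaling already trims extreme genes, so this check could hardly lose calls and does not decide on a few abundant genes as a cause. With the section total in the model, 179 calls were kept and 131 changed sign. The amount of tissue in a section and its position cannot be told apart here, because the median total was 14600693.5 in the middle and 2438734 at the ends. No biological explanation was tested.

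Calls were shared between axes more often than expected in 14 pairs of lists. Within deciles of mean expression, 13 of the 14 kept an adjusted p under 0.05, the exception being posterior and dorsal genes (adjusted p = 0.0883), which argues against abundant genes being called everywhere as the whole cause. Summed over these pairs there were 130 shared rows, and an identifier can be counted in several pairs. Within their pairs, 97.7% had distinct first parts, which argues against rows with the same first part being counted repeatedly. Sequences were not compared, so near-identical rows with different first parts stay open. Cells of 1 type placed on several axes may account for the sharing, which these values (13 and 97.7%) leave open and which was not tested, since identifiers carry no names.

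Each fit was run on 100 orders of the same sections per series, the real one included, and at most 4 orders reached the real count in any test. For the anterior-posterior end and middle tests and the right-left end test, a shuffled order exceeded the real count, so chance was not firmly excluded there. In the other tests no shuffled order reached it, and chance could be excluded for each taken alone. This assumes that sections are exchangeable and makes no adjustment over the tests. Neighbouring sections resemble each other, so shuffled orders are rougher than any smooth drift along the series, and a drift with library order is not covered. In the anterior-posterior series, 1 order gave 3114 position-dependent genes or more (highest other 998), 3 gave 336 end genes or more (highest other 813) and 4 gave 219 middle genes or more (highest other 279). In the dorsal-ventral series 1 order each reached 2996, 146 and 1664 genes, with 64, 1 and 2 as the highest others. In the right-left series 1 order reached 1510 position-dependent genes (highest other 470), 2 reached 7 end genes (highest other 32) and 1 reached 163 middle genes (highest other 33). The shuffled order with 32 genes gave several times the real count. It may point to some structure among the right-left sections, but a single order cannot show this, and it was not tested.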
